A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

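Insertion sites of the Ty1 retrotransposon were measured in 1 haploid and 1 diploid library of the budding yeast Saccharomyces cerevisiae by TIP-seq, a method that amplifies and sequences the genomic DNA next to a transposon end. Per the labels' protocols, a galactose-inducible Ty1 element carrying a short sequence tag was expressed from a plasmid. The protocols describe 96 inductions for 48 h at 22 °C, started from 12 colonies, with 8 cultures pooled per DNA preparation. The plasmid was then lost, plasmid-free cells were selected on 5-fluoroorotic acid, and the DNA was cut with MseI and BglII before adaptors were ligated. The diploid library carries the same protocol and genotype text as the haploid one, including a mating type of a haploid strain, so how the diploid was made is not given in the sources used here.

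The authors deposited 1 list of positions per library, with a chromosome, a position, a strand, a whole-number count of clones and a sequence of 30 bases. The deposited counts are raw numbers of clones per position, which neither the file headers nor the labels define further. They were taken here as the support of a site and were not normalized. Bowtie is named as the aligner in the submitters' processing notes, without a version. The genome build, the mapping settings and the filter named in the deposited files are not given in the sources used here. A site was 1 combination of chromosome, position and strand. Overlapping deposited sequences fixed the coordinate system: a sequence starts at the listed position on the plus strand and ends just before it on the minus strand, and the 733137 bases covered this way had no conflicts. The centre of the 5 bp that follow the junction was used as the location of the insertion, since Ty1 duplicates a target of 5 bp.

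Gene names and neighbourhoods came from a RefSeq gene table of the R64 assembly, which gives no sequence, isotype or anticodon. Whether this table fits the files was checked by looking for start and stop codons in the deposited sequences. Of 86 segments on the 15 chromosomes used, 54 had enough codons for a settled answer, and their offsets lay between -8 and 5 bp. On chromosome 11 the offset reached -358 bp. Chromosome 11 and the mitochondrial genome were therefore left out of every result that needs a gene. In the settled segments distances to genes are exact only to about 8 bp. For the other segments, including that of chromosome 1, no such bound was shown. Coordinates in the text are those of the files, in an unnamed build.

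Upstream means the side of the 5′ end of the mature tRNA or other RNA, and a site within 1 kb of several such genes was given to the nearest. A site upstream of any tRNA gene was not counted as downstream of another, even where that other gene was nearer. Protein-coding genes were taken from start to end of the table's entry, introns included. No genome sequence was used here, so the planned random sites matched on MseI sites were replaced by 1000000 positions drawn uniformly over the 15 chromosomes, and base composition was compared with bases 11 to 30 of the deposited sequences. Observed shares were tested against 1000 random sets, for which the smallest two-sided p is 0.002. Each set was a binomial draw of independent sites at the share of the random positions. Shares have Wilson 95% intervals, and the upstream share of upstream plus downstream sites has an exact binomial interval. Libraries were compared with two-sided Fisher's exact tests, and Benjamini-Hochberg adjustment was applied over the 259 tRNA genes. The repeat along the upstream DNA was the lag of the highest autocorrelation peak between 40 and 250 bp after smoothing with a kernel of 10 bp. Its spread, and that of the strand share, came from 1000 bootstrap draws of tRNA genes. Rank correlations were tested with 100000 permutations.

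With 1 library per group there were no replicates, so every test compares these 2 libraries and not the conditions. The counts come after PCR, and whether 1 clone stands for 1 molecule is not given, so they may not count molecules. The intervals cover counting error over sites or, for bootstraps over tRNA genes, the spread among genes. None covers the spread between cultures. Before the data were examined, gene lists were fixed for essential, dispensable, marker, silenced or subtelomeric, and other RNA polymerase III (Pol III) genes. The rule for named genes was also fixed then. It takes the 10 tRNA genes with the most upstream sites per library, the 5 with the fewest, up to 5 with the lowest p in each direction, and all other Pol III genes. It also takes the 5 coding genes and the 5 windows of 1 kb over 2 kb from any Pol III gene with the most sites, and the marker genes. Whether the DNA upstream of the tRNA genes with the fewest sites is unique was not analysed here, and the 5 were taken over both libraries together.

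Alternatives fixed beforehand were a minimum of 2 clones, merging of sites within 5 bp on a strand, weighting by clones, thinning of haploid sites to the diploid number, windows of 500 bp and 2 kb, isolated tRNA genes, a kernel of 5 bp, omission of the 5 tRNA genes with the most sites, the dispensable list as reference and a tolerance of 2 bp for shared positions. A restriction to uniquely matching sequences was not run for want of a genome. The scripts were tested on simulated sites for the comparison of tRNA genes between libraries. There, 17 of 20 genes changed 3-fold among 259 were recovered and 1 unchanged gene was called, while 0 genes were called when no change was made. A repeat of 165 bp was found at 166 bp, and an upstream share made at 50% was found at 47.8%, so the share was understated there. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.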

Results

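Positions of newly integrated Ty1 elements were listed for a haploid and a diploid culture of budding yeast that had expressed a tagged Ty1 element from a plasmid. The haploid library listed 38733 insertion sites supported by 1165871 clones, and the diploid library 32492 sites supported by 147659 clones. The median site had 8 clones in the haploid and 2 in the diploid library. Sites with a single clone made up 13.5% of the haploid and 49.1% of the diploid list. In the haploid library the highest site had 8210 clones and in the diploid library 1180, and the top 1% of sites held 29.8% and 30.4% of the clones. After chromosome 11 and the mitochondrial genome were set aside, 36184 haploid and 30043 diploid sites were compared with genes. There was 1 library per group, so no value below has a replicate. The intervals cover counting error over sites or the spread among tRNA genes, not the spread between cultures.

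The series asks where Ty1 integrates relative to genes transcribed by Pol III, the polymerase of tRNA genes. In the haploid library 24464 sites, or 67.6% (95% interval 67.1 to 68.1%), lay within 1 kb upstream of 1 of 259 tRNA genes. In the diploid library the number was 14884, or 49.5% (48.98 to 50.1%). Random positions fell there in 2.24% of cases, so the haploid share was 30.2 times and the diploid share 22.1 times the random one. None of the 1000 random sets, drawn as independent sites at that random share, reached either share. The haploid share exceeded the diploid one by 18.1 percentage points (17.3 to 18.8). With 2 or more clones per site the shares were 67.9% and 60.5%, a difference of 7.43 points (6.50 to 8.36). With sites weighted by clones they were 82.2% and 73.9%, a difference of 8.26 points. Among sites with 5 or more clones, 24055 in the haploid and 4524 in the diploid library, the order was turned, with 68.9% and 81.6%, a difference of -12.7 points (-13.9 to -11.4). With haploid clones thinned to the diploid total the difference was 20.1 points over all sites and 1.05 points among those with 5 or more clones (median p = 0.173 over 100 draws, Fisher's exact test), where it was not detectable.

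**Figure D1:**
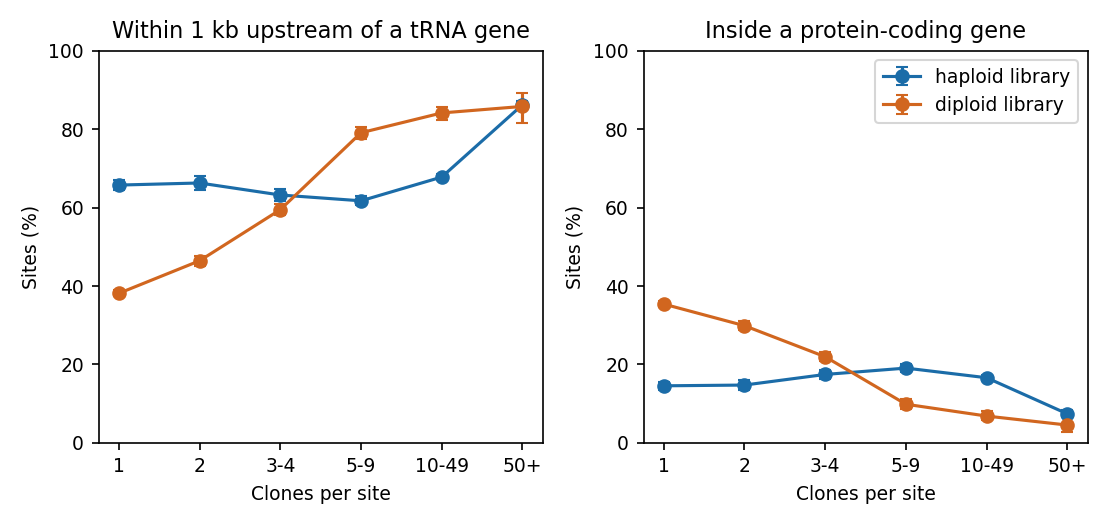
Share of sites (%) within 1 kb upstream of a tRNA gene (left) and inside a protein-coding gene (right) against the number of clones per site, for the haploid and the diploid library, with Wilson 95% intervals as bars. From sites with 1 clone to sites with 50 or more, the tRNA-upstream share went from 65.7% to 86.2% in the haploid library, with a fall to 61.7% at 5 to 9 clones in between, and rose at each step from 38.1% to 85.8% in the diploid library.

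Sites crowded on the upstream side of tRNA genes and were far fewer on the downstream side. The downstream side still held 8.22% of haploid and 6.90% of diploid sites. Its share of random positions was not computed, but the upstream window took 2.24% of them, so the downstream side was not shown to be avoided. Within 1 kb downstream there were 2976 haploid and 2074 diploid sites, so the upstream side held 8.22 times as many sites in the haploid library and 7.18 times as many in the diploid library. The upstream share of both sides was 89.2% (exact 95% interval 88.8 to 89.5%) and 87.8% (87.3 to 88.3%). Over all sites the odds of lying upstream were 1.15 times higher in the haploid library (Fisher's exact test, p = 8.73e-06), but the order was turned at 89.2% and 90.7% with 2 or more clones per site and at 89.5% and 95.6% with 5 or more. The first 50 bp next to the tRNA gene were almost empty, with 35 sites in each library, or 0.143% of upstream sites in the haploid and 0.235% in the diploid. The zone from 100 to 200 bp held 26.4% and 27.9% of upstream sites, and the zone up to 400 bp held 62.3% and 63.5%.

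Within this region the sites formed regularly placed peaks, the feature that the series links to nucleosomes, the protein spools on which DNA is wound. In the haploid library the maxima lay 102 bp (bootstrap SD 1.30), 174 bp (SD 2.11), 277 bp (SD 2.11) and 351 bp (SD 2.14) upstream of the tRNA gene. The diploid maxima lay at 103 bp (SD 1.47), 176 bp (SD 1.57), 276 bp (SD 2.20) and 351 bp (SD 2.34). These SDs come from resampling of tRNA genes. They leave out the offset between gene table and files, up to 8 bp in settled segments and not bounded elsewhere, which both libraries share. Further maxima at 463, 519 and 633 bp in the haploid and 468, 520 and 634 bp in the diploid library were placed less precisely, with SDs of their position from 6.62 to 9.29 bp over the bootstrap draws. The peaks came in pairs, with gaps of 72 and 74 bp inside the first pairs and 103 and 112 bp between pairs in the haploid library. The corresponding diploid gaps were 73 and 75 bp, and 100 and 117 bp. The repeat of the whole pattern was 173 bp (95% bootstrap interval 171 to 176) in the haploid and 172 bp (170 to 175) in the diploid library. Both intervals overlap, and a difference in repeat length was not detectable.

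**Figure D2:**
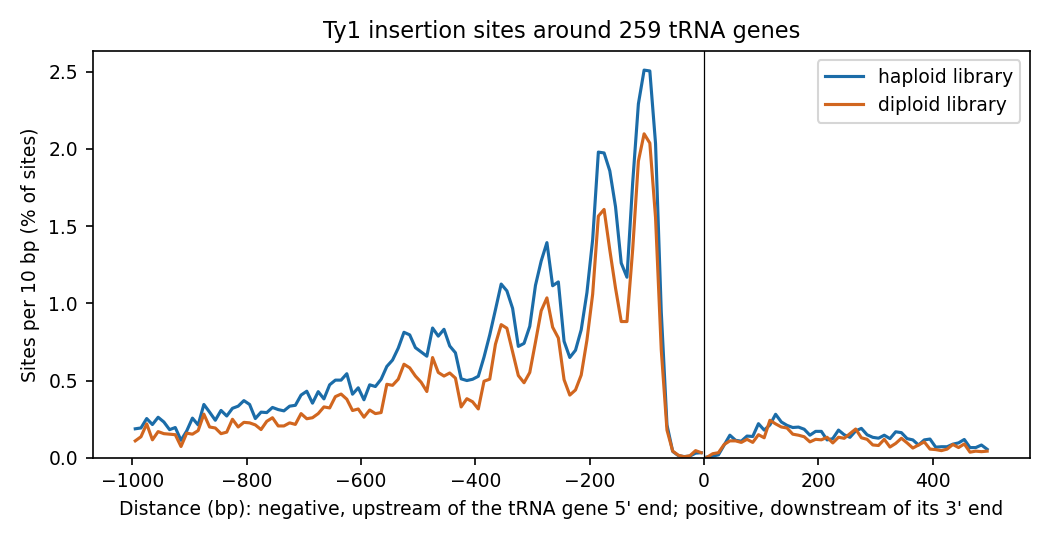
Sites per 10 bp (% of all sites used in the library) against the distance in bp from 259 tRNA genes, negative upstream of the 5′ end and positive downstream of the 3′ end, for the haploid and the diploid library. The first maxima lie 102 and 103 bp upstream, and both curves fall close to 0 next to the gene.

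The strand listed for an insertion was nearly balanced with respect to the tRNA gene, with an excess close to it. Over the whole 1 kb, 53.1% of haploid sites (95% interval over tRNA genes 52.2 to 54.0%) and 52.7% of diploid sites (51.5 to 54.0%) had the strand of the tRNA gene. From 60 to 140 bp the same-strand share was 56.3% (54.5 to 58.2%) in the haploid and 58.1% (55.3 to 61.1%) in the diploid library, and from 140 to 220 bp it was 56.8% (54.7 to 59.1%) and 55.7% (52.4 to 59.1%). Beyond 400 bp it was 50.4% (48.9 to 51.9%) and 49.8% (47.9 to 51.4%), with intervals that include 50%. Which Ty1 end faces the listed sequence is not given in the sources used here, so the strand is not translated into an orientation of the element. With sites weighted by clones the same-strand share over 1 kb was 57.2% in the haploid and 58.1% in the diploid library. After sites within 5 bp of each other on a strand were merged, the diploid share was 50.7% and did not differ from 50% in the bootstrap over tRNA genes.

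Single tRNA genes differed widely in their number of upstream sites, and their ranking was largely shared by the libraries. A tRNA gene had a median of 88 upstream sites (quartiles 40 and 133) in the haploid and 54 (quartiles 25 and 81) in the diploid library, and the 26 genes with the most sites held 23.4% and 24.8% of them. YNCG0042C led both libraries with 346 haploid and 224 diploid sites, its haploid sites spanning positions 878879 to 879805 of chromosome 7. On chromosome 5, YNCE0023W had 341 and 193 sites, with the haploid ones from 437733 to 438623. The neighbours YNCI0009W and YNCI0008C on chromosome 9 had 271 and 234 haploid sites and 217 and 170 diploid sites. SUP56, a leucine tRNA gene on chromosome 1, had 237 and 159 sites, and YNCJ0019C on chromosome 10 had 276 and 196. The other leading genes of the haploid library were YNCG0009C with 256 haploid sites, SUF9 with 231, YNCE0022C with 223 and YNCJ0011W with 208. Among the 10 leading genes of each library 8 were shared, and YNCN0004W with 150 and YNCG0004W with 142 diploid sites were among the 10 in the diploid library only. At the other end, YNCB0016W, YNCD0012W, YNCJ0012W, YNCJ0013C and YNCN0008C had 0 sites in both libraries. For the first 4 of these another tRNA gene on the same strand lay 10 bp upstream and took the sites by the rule of the nearest gene, so their 0 does not measure their use. Low counts of other genes need not measure use either. YNCG0025C had 4 haploid sites, from position 561834 to 561846 of chromosome 7. A window of 1 kb about 6.26 kb upstream of it, beyond the Ty1 gene YGR038C-B, held 79. Across tRNA genes, which are not independent replicates, Spearman's rho was 0.931 (permutation p = 1e-05, the smallest 100000 permutations can give). Both libraries used the same windows, so differences between genes in the upstream DNA that could be listed may also raise rho.

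Use differed between the libraries for 16 of 259 tRNA genes at an adjusted p below 0.05 in Fisher's exact test, and for 42 at an unadjusted one. In the haploid library 12 of them had the higher share. SUP61, a serine tRNA gene, had 134 haploid and 27 diploid sites (odds ratio 3.03, exact test, adjusted p = 1.76e-06). YNCO0008W had 68 and 16 sites (odds ratio 2.59, exact test, adjusted p = 0.0119), YNCE0016C had 89 and 25 and YNCD0007C had 92 and 26. YNCC0005W had 200 and 74 sites (odds ratio 1.65). The diploid library had the higher share for 4 genes. YNCE0027C had 107 haploid and 116 diploid sites (odds ratio 0.559, exact test, adjusted p = 0.00209) and YNCJ0018W had 10 and 25 (odds ratio 0.243, adjusted p = 0.00613). YNCL0051C, with 86 and 85 sites, and YNCI0009W had odds ratios of 0.614 and 0.757. These calls compare the sites of 2 libraries. The count was 8 with haploid clones thinned to the diploid total or with 5 or more clones per site, and 0 after sites within 5 bp were merged or when both conditions on clones were combined.

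**Figure D3:**
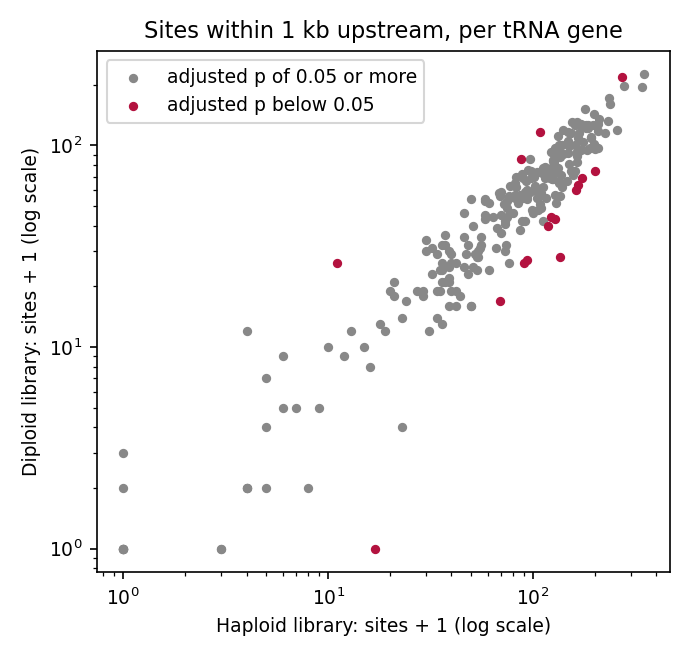
Sites within 1 kb upstream of each of 259 tRNA genes, haploid library (x axis) against diploid library (y axis), both as sites + 1 on log scales, with the 16 genes of adjusted p below 0.05 in red. The points follow 1 band, with a Spearman rho of 0.931.

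Upstream sites were also listed for other genes made by Pol III, but not for all of them. Upstream of SCR1, the RNA of the signal recognition particle, there were 313 haploid and 162 diploid sites, the haploid ones at positions 441109 to 441913 of chromosome 5. RPR1, the RNA of RNase P, had 152 and 83 sites, with the haploid ones at positions 118182 to 118965. SNR52, a small nucleolar RNA gene, had 126 and 81 (haploid positions 431419 to 432217), and SNR6, the U6 RNA gene on chromosome 12, had 59 and 30 (haploid positions 365237 to 366169). ZOD1 had 1 and 2 upstream sites and RNA170 had 3 and 0. No upstream site was listed for any of the 5S ribosomal RNA genes RDN5-1 to RDN5-6. Within 1 kb downstream of RDN5-1, however, the haploid library had 292 sites from position 459839 to 460566 and the diploid library 291 sites from 459837 to 460584. RDN5-6 had 0 and 3 downstream sites and the other RDN5 genes had 0. Because the ribosomal DNA is repeated, the copy that carried such an insertion is uncertain. The mapping settings are not given, so the lack of upstream sites at RDN5 genes cannot be told apart from an effect of mapping.

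All these genes together took 654 haploid sites, or 1.81% (1.68 to 1.95%), and 358 diploid sites, or 1.19% (1.08 to 1.32%), against 0.107% of random positions. The shares were 16.9 and 11.1 times the random one, and no random set reached either. The haploid share was 0.616 points higher (0.431 to 0.80, Fisher's exact test, p = 9.27e-11). With 2 or more clones per site the difference was 0.108 points (Fisher's exact test, p = 0.419), and with 5 or more it was -1.20 points (p = 1.98e-06). With sites merged within 5 bp the shares were 0.912% and 0.633%, and with sites weighted by clones 4.52% and 3.12%, a difference of 1.40 points that was not past the threshold in its bootstrap.

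Protein-coding genes were avoided, more so in the haploid library. They contained 5706 haploid sites, or 15.8% (15.4 to 16.1%), and 8466 diploid sites, or 28.2% (27.7 to 28.7%), where random positions gave 72.9%. Among sites not upstream of a tRNA gene the coding share was 34.9% and 49.2%, against 74.0% of such random positions. The same 5 coding genes had the most sites in both libraries, and each lay upstream of a Pol III gene. YER137C, next to SCR1, contained 217 haploid and 138 diploid sites. YIL014C-A, next to YNCI0009W, contained 164 and 129, and YER135C, next to YNCE0023W, contained 141 and 46. YHR125W contained 79 and 50. YCL021W-A contained 97 and 47, but it lay about 1.09 kb upstream of YNCC0001C, with no tRNA gene within 1 kb. The haploid coding share was below the diploid one by -12.4 points (-13.0 to -11.8). With 5 or more clones per site the difference was 7.62 points (6.67 to 8.52), with 15.9% haploid and 8.24% diploid, and with that minimum after thinning of haploid clones it was 0.648 points (median p = 0.257 over 100 draws, Fisher's exact test). Weighting by clones gave shares of 9.24% and 12.8%, and merging within 5 bp 24.2% and 37.5%.

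A haploid cell has a single copy of each gene, so an insertion that breaks an essential gene can be lost from a haploid culture and not from a diploid one. Genes of the essential list contained 88 haploid and 375 diploid sites, or 0.204 and 0.871 per kb, and sites were found in 69 and 158 of the 239 members on the chromosomes used. RPC17, a subunit of Pol III, had 0 haploid and 15 diploid sites, and YEF3, a translation elongation factor, had 0 and 10, while PRP6, a splicing factor, had 2 and 11. These 3 examples were chosen after their values were seen, and RPC17 and PRP6 lie within 1 kb of a tRNA gene. Genes of the dispensable list had 1.07 and 1.44 sites per kb, with sites in 45 and 73 of 94 members. All coding genes outside the essential list had 0.713 and 1.02 sites per kb. Essential genes thus held 1.54% of haploid coding sites (1.25 to 1.90%) and 4.43% of diploid ones (4.01 to 4.89%), and random coding positions fell there in 5.17% of cases. The odds ratio was 0.338 (0.264 to 0.429, Fisher's exact test, p = 4.06e-23), and 0.404 (0.300 to 0.542) with 2 or more clones per site. It was 0.216 without sites whose sequence starts with GATC or TACC and 0.208 with sites weighted by clones. Only 6 diploid essential sites had 5 or more clones, against 53 haploid ones, and at that depth the odds ratio was 0.862 (0.367 to 2.47, Fisher's exact test, p = 0.647).

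The silenced and subtelomeric list, with 23 of 24 genes measured, had 11 haploid and 14 diploid sites, or 0.709 and 0.902 per kb. Marker genes held at most 1 haploid and 5 diploid sites each. HIS3, a histidine synthesis gene deleted in the labelled strain, had 0 haploid and 3 diploid sites, and URA3, a uracil synthesis gene, had 0 and 5. The 3 diploid sites in HIS3 seem to go against the genotype label, which is the same for both libraries, but their place relative to the deletion was not checked. Whether the diploid carries a HIS3 allele is not given in the sources used here. The galactose genes GAL1, GAL10 and GAL7 had 0, 1 and 1 haploid sites and 3, 3 and 5 diploid sites. CAN1, the arginine permease, had 1 and 0, and HO, the mating-type switching nuclease, had 1 and 3.

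Over all sites, a larger share of diploid than of haploid sites lay away from Pol III genes. Over 2 kb from any Pol III gene lay 5258 haploid sites, or 14.5% (14.2 to 14.9%), and 10547 diploid sites, or 35.1% (34.6 to 35.6%). With 2 or more clones per site the shares were 14.1% and 24.7%, and with 5 or more the order was turned, at 13.0% and 5.97%, or 4.46% haploid at that depth after thinning of haploid clones. The sites far from Pol III genes included some dense windows of 1 kb. The window starting at position 160000 of chromosome 1, beside the Ty1 gene YAR009C, held 107 haploid and 53 diploid sites. On chromosome 7 the window at 535000, beside the Ty1 gene YGR027W-B, held 81 and 40, and the window at 568000, beside the Ty1 gene YGR038C-B, held 79 and 55. The window at 144000 of chromosome 6, beside SPB4, a ribosome assembly helicase, held 78 and 55. On chromosome 16 the window at 63000, inside YPL257W, held 72 and 44, and the window at 443000, beside YPL060C-A, held 54 and 41.

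The same exact base was often hit in both libraries. Of the 32492 diploid positions, 12709 or 39.1% (38.6 to 39.6%) were listed on the same strand in the haploid library. When each diploid site was moved by 5 to 50 bp, 2374 positions were shared on average (SD 43.7 over 1000 draws, highest 2511), so the observed number was 5.35 times higher (permutation p = 0.000999, the smallest these draws can give). Upstream of tRNA genes 65.9% of diploid positions were shared and elsewhere 13.6%. Of diploid positions with 1 clone 23.1% were shared, and of those with 5 or more clones 88.4%. The count does not separate repeated use of a base from DNA carried over between libraries.

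The bases at the insertion formed a weak pattern that reached beyond the 5 bp that Ty1 duplicates and was nearly symmetric within them in the haploid library, less so in the diploid one. Counted from the junction, A and T filled the middle, with 40.8% A and 42.7% T at the third base of the haploid sequences. At the first base A reached 38.5% and G 25.4% while T fell to 16.8%, and at the fifth base T reached 38.7% and C 25.1% while A fell to 16.1%. The diploid library had 42.8% A and 20.6% G at the first base and 34.3% T, 26.1% C and 19.9% A at the fifth. Outside the 5 bp, A reached 42.6% in the haploid and 40.4% in the diploid library at the sixth base, and T 44.2% and 45.1% at the base before the junction, for the 30413 and 19179 sites where it was known from other sequences. Relative to bases 11 to 30, the sixth base carried 0.0503 and 0.0423 bits, more than the 0.0468 and 0.0256 bits of the fourth, and the eighth 0.0330 and 0.0305 bits. The information over the first 5 bases was 0.442 bits (bootstrap SD 0.00571) in the haploid and 0.253 bits (SD 0.00552) in the diploid library. With 5 or more clones per site it was 0.483 and 0.633 bits, and with sites weighted by clones 0.700 and 0.551 bits.

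**Figure D4:**
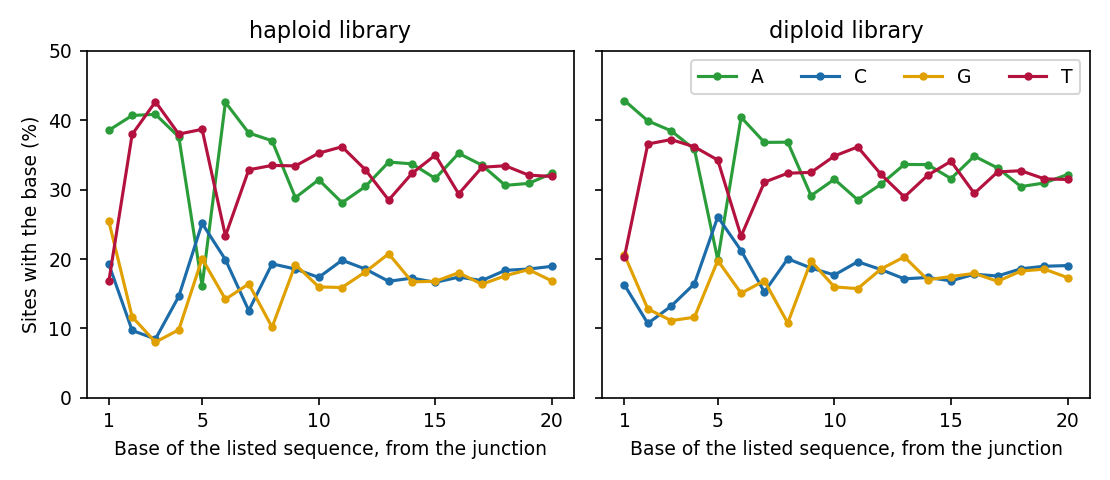
Share of sites (%) with A, C, G or T at bases 1 to 20 of the listed sequence, counted from the junction, in the haploid (left) and diploid (right) library. A stands at 16.1% (haploid) and 19.9% (diploid) at base 5 and at 42.6% and 40.4% at base 6.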

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

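The tests on sites with 5 or more clones, with and without thinning, and the tests of whether GATC and TACC starts lie upstream of tRNA genes were chosen after the results were seen. Thinning alone, the removal of GATC or TACC starts and the tests on the fifth base, dispensable genes and sites with 1 clone were added after the data were examined, with their bounds set before their own results. Mitochondrial positions were outside every comparison, yet 181 haploid sites (0.467%) and 500 diploid sites (1.54%) were listed there, above the 0.00775% and 0.00923% that a count of 0 allows. In the haploid library 28.2% of the mitochondrial sequences (51 of 181) began with TTAA, the MseI site, against 0.379% of nuclear ones. In the diploid library 1.40% (7 of 500) did, against 0.172%. A share expected from the base composition of mitochondrial DNA was not computed, so the nuclear shares do not show whether the diploid 1.40% is an excess. The odds of lying upstream rather than downstream of a tRNA gene differed between the libraries by an odds ratio of 1.15, an order that turned with 2 or more clones per site (89.2% haploid and 90.7% diploid upstream), and the shares upstream of other Pol III genes differed by 0.616 points, which fell to 0.108 points with 2 or more clones and turned to -1.20 points with 5 or more.

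The share upstream of tRNA genes was 18.1 points higher in the haploid library. A smaller number of diploid clones does not account for this, because the lowest difference was 19.8 points in 100 draws with haploid clones thinned to the diploid total. Nor do GATC and TACC starts together, because 18.5 points (17.7 to 19.2) remained without both. Without TACC starts alone the shares were 67.7% haploid and 50.9% diploid. The difference may lie in positions with few clones, since with 5 or more clones per site after thinning it was 1.05 points (-0.444 to 2.55), on 5749 haploid and 4524 diploid sites. Whether such diploid positions are Ty1 junctions cannot be told apart from a real spread of insertions, because away from tRNA genes the information over the first 5 bases of sites with 1 clone was 0.509 times the haploid one (0.427 to 0.585), an interval that includes the bound of 0.5. In the diploid and haploid library it was 0.272 bits (SD 0.0148) and 0.586 bits (SD 0.0308) there with 2 to 4 clones, 0.576 bits (SD 0.0491) and 0.552 bits (SD 0.0157) with 5 or more, and upstream of tRNA genes with 1 clone 0.289 bits (SD 0.0108) and 0.256 bits (SD 0.0144), and an effect of ploidy stays open. These values by number of clones leave out sites that start with GATC or TACC, unlike the values over all sites.

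Coding genes had a haploid share that was -12.4 points relative to the diploid one, and essential genes an odds ratio of 0.338. Loss of haploid cells with a broken essential gene cannot be the whole cause, since the haploid share of sites in dispensable genes was also lower, 0.619 times the diploid one (0.514 to 0.745). The coding difference may lie in positions with few clones, since it was 0.648 points (-0.450 to 1.73) with 5 or more clones per site after thinning, while thinning alone left -12.9 points. The essential odds ratio was 0.404 (0.300 to 0.542, Fisher's exact test, p = 2.51e-10) with 2 or more clones, where the coding difference was -5.30 points, and 0.308 with thinning alone. Loss of cells as its cause stays open, because at 5 or more clones it was 0.862 (0.367 to 2.47) with only 6 diploid sites and, after thinning, 0.239 at that depth (median p = 0.0754, Fisher's exact test).

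Some sites began with a fixed sequence of 4 bases, mostly in 1 library. GATC opened 1039 haploid sequences (2.68%) and TACC 924 diploid ones (2.84%), and 76.2% and 75.3% of those used lay in coding genes. A preference of integration for these sequences goes against their places, as 7.06% of the GATC sites and 3.72% of the TACC sites lay upstream of a tRNA gene, compared with 69.3% and 50.9% of the other sites. TACC also opened 84 haploid sequences, with 33.8% of those used upstream against 67.7% of other sites. GATC opened 87 diploid ones, with 53.0% upstream against 49.5%. Ends cut by BglII, which leaves GATC followed by T, may account for the haploid GATC sites, since 90.6% had T as the fifth base (886 of 978) against 37.2% of other sites. No other biological explanation was tested, and the origin of the TACC starts stays open.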

How the results depend on the processing

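The alternatives with a minimum of 5 clones, with haploid clones thinned to the diploid total, without GATC or TACC starts and with chromosome 11 were chosen after the data were seen, and the others before. Under the alternatives fixed beforehand 103 values kept their direction and their side of the threshold or moved by less than their spread, 8 moved further and 3 lost their call. Under the added ones the numbers were 55, 8 and 4, and 4 changed sign. The tRNA-upstream share was above random in every alternative run, from 48.9% to 82.7% in the haploid and from 34.3% to 81.6% in the diploid library, and rho across tRNA genes stayed between 0.869 and 0.936. With 5 or more clones per site, the haploid minus diploid differences were -12.7 points upstream of tRNA genes, -1.20 points upstream of other Pol III genes and 7.62 points in coding genes, the essential odds ratio was 0.862, 8 tRNA genes differed, the diploid repeat was 174 bp and the base information was 0.483 bits haploid and 0.633 bits diploid. At that depth after thinning of haploid clones, the differences were 1.05, 0.422 and 0.648 points in the same order, the odds ratio was 0.239 and 0 tRNA genes differed, on far fewer haploid sites by construction. Thinning alone left 8 tRNA genes that differed. With 2 or more clones per site the other Pol III difference was 0.108 points (Fisher's exact test, p = 0.419) and the base information 0.464 bits haploid and 0.343 bits diploid. The upstream share of sites on both sides of tRNA genes, higher in the haploid library over all sites, was the higher one in the diploid library with 2 or more clones (90.7% against 89.2%) and with 5 or more (95.6% against 89.5%), and at 5 or more after thinning it was 95.3% haploid. Merging of sites within 5 bp gave 0.669 and 0.265 bits, a diploid repeat of 170 bp, a diploid same-strand share of 50.7% and 0 tRNA genes that differed, and it shrinks dense regions by construction. Weighting by clones raised the same-strand share to 57.2% haploid and 58.1% diploid and gave 0.700 and 0.551 bits and an other Pol III difference of 1.40 points, not past the threshold in its bootstrap. Without GATC and TACC starts the base information was 0.433 and 0.309 bits. Where no cause is named here, the cause was not tested. Weighting gives no count of differing tRNA genes or of shared positions, base information was not recomputed under thinning, and the alternatives on uniquely matching sequences were not run. No paired analysis was possible because each group holds 1 library. The depth of the diploid library, with a median of 2 clones per site, limits every statement on rarely seen positions.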

Other observations

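The count of pairs of junctions and the test on windows far from Pol III genes were chosen after the results were seen, and the test on coding DNA before. Junctions on opposite strands were often 5 bp apart, the length of the target that Ty1 duplicates. In the haploid library 5935 minus-strand junctions lay 5 bp after a plus-strand junction, which was 2.40 times the highest count at any other distance up to 20 bp (2473), and in the diploid library 2612 did, 2.69 times the highest other count. A cause of this spacing was not tested.

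Upstream of tRNA genes, fewer insertion sites were listed in coding DNA even at equal distance. Within 1 kb upstream, 23.7% of the DNA was coding, and per bp it held 0.362 times as many haploid sites as other DNA in the same steps of 50 bp (bootstrap interval 0.256 to 0.492). In the diploid library the ratio was 0.390 (0.275 to 0.528). The distance to the tRNA gene is therefore unlikely to be the whole source of the low coding share, and a cause was not tested. Because no restriction to uniquely matching sequences was run, poor mapping in repeated coding DNA, such as Ty genes, may lower the ratio.

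The dense windows far from Pol III genes may be targets of tRNA genes that a Ty copy of the annotated genome holds apart. All 6 named windows lay upstream of a tRNA gene with a coding gene of over 3 kb in between. The window at 144000 of chromosome 6 lay about 6.44 kb upstream of the tRNA gene YNCF0004C with YFL002W-A in between, and that at 63000 of chromosome 16 lay about 6.73 kb upstream of YNCP0001C with YPL257W-B in between. The window at 535000 of chromosome 7 lay about 5.85 kb upstream of YNCG0022W with YGR027W-B in between, but another tRNA gene, YNCG0021W, was nearer, with the window about 3.32 kb downstream of it and no coding gene of that length in between. A coding gene of 5 to 5.6 kb, the length of a Ty coding region, lay within 2 kb upstream of 33 tRNA genes. These had 27.5 haploid sites per gene from 5 to 8 kb upstream, against 2.11 for the other 226 tRNA genes, a ratio of 13.0 (bootstrap interval 5.65 to 27.5), and the diploid ratio was 5.40 (2.87 to 8.78). The densest window, at 160000 of chromosome 1, was missed by the length rule of this split. The Ty1 gene YAR009C between it and TGA1 is 3.59 kb long, so TGA1 counted among the other genes. The coding gene YAR010C listed next to YAR009C, 1.32 kb long and within 1 kb of a tRNA gene, was not added to that length. Without the tRNA genes whose region meets a named window, 28 and 225 genes gave a haploid ratio of 9.01 (4.27 to 15.3) and a diploid ratio of 3.03 (1.69 to 4.71). Whether the strain carries these copies was not analysed here.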
